A study of Mus musculus with 5 samples.

How the data were processed

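Kidneys came from wild-type male mice aged 60 days, per the labels' protocols. Nuclei were isolated, chromatin was fixed with 1% formaldehyde for 10 min and sheared by sonication, and libraries were made from 1 ng of immunoprecipitated DNA with 10 amplification cycles and sequenced as paired reads of 40 cycles. The antibody was directed against HNF1B, and the label of the input sample carried the same antibody entry. The 4 immunoprecipitated samples formed 1 group, numbered 1 to 4 as in their titles, and the input formed another with no list analysed here. The library names of replicates 2 and 4 share a number whose meaning was not given in the sources used here. The labels did not state that the 4 libraries came from 4 animals, so spreads over libraries describe these libraries, not a population of animals. The p-values were computed over genes or sites and do not carry the variation between libraries or animals.

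The submitters' processing notes named FastQC 0.11.5, Bowtie2 2.3.3.1, deepTools without a version and genome build mm10. The names of the deposited lists pointed to binding events of the GPS step of GEM, and the version, the settings, the control library and any filter on duplicates or problem regions were not given in the sources used here. The authors deposited 1 list per library, and whether the libraries were called separately or jointly was not given in the sources used here. The comparison of the lists with shifted lists takes them as separate calls. Every event spanned 201 bp. The signal of an event is the authors' value, read here as the number of reads assigned to the event, with no scaling between libraries, and it ranged from 22 to 8468.5. The deposited −log10 p and −log10 q of each event were also the authors' values, with a lowest −log10 q of 2 and an upper limit of 999, reached by 3134 events of library 1 and by 43, 7 and 2 events of libraries 2, 3 and 4. A deposited score, a rescaling of the signal within each list, was not used.

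The position of an event was taken as its centre, counted from 1 in mm10. Events off chromosomes 1 to 19, X and Y were left out. Event centres no more than 100 bp apart were chained into 1 site, and a site was called shared when all 4 libraries had an event in it. For each library the strongest event of a site gave its signal. Strength was that signal over the library's median at shared sites (537, 202, 169 and 112 in libraries 1 to 4), averaged over the 4 libraries with its SD. At 13.8% of shared sites library 1 had more than 1 event, against 5.50%, 2.20% and 4.78% in libraries 2 to 4, which lowers the strongest event where reads were divided.

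Chance overlap was measured by 100 circular shifts of a list along each chromosome by at least 1 Mb. For each ordered pair of libraries the share of events with an event of the other library within 100 bp was divided by its mean over the shifts, then averaged per library. Gene positions came from a RefSeq gene table of the GRCm38 assembly, the same primary sequence as mm10, with the start and end of 21883 protein-coding genes. It held neither strand nor exons, so distances were taken to either end of a gene, not to transcription starts as first planned, and sites were not assigned to exons, introns or untranslated regions. No genome sequence was used here, so the planned searches for the HNF1 recognition sequence were not run.

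A gene was counted as having a site when a shared site lay within 10 kb of either end. A total of 6485 genes (29.6%) did. Before the data were examined, 23 gene lists were fixed, with 714 entries. Of these, 713 matched the gene table, 6 of them by an older symbol, and 1 did not. The lists covered reported HNF1B targets, cystic and tubulointerstitial disease, tubule injury and inflammation, renal transcription factors, and 4 nephron segments (proximal tubule, thick ascending limb, distal convoluted and connecting tubule, collecting duct). They also covered podocytes, endothelium, stroma and fibrosis, immune cells, hepatocytes, neurons, striated muscle, ribosomal proteins, oxidative phosphorylation, fatty acid oxidation, cholesterol synthesis, glycolysis, cilium assembly, drug metabolism and transport, and the cell cycle. Each list was set against all other protein-coding genes with a two-sided Fisher's exact test, adjusted over the 23 lists by the Benjamini-Hochberg method, and odds ratios were computed after adding 0.5 to each cell. Genes are not independent replicates, and members of 1 cluster can share a site. Some genes are on more than 1 list, so the results of different lists are not independent. The strength of a gene was that of its strongest shared site within 10 kb of an end, so genes with more sites have more chances of a strong one. The mean log2 strength of list members with a site was compared with 10000 random draws of genes with a site. This was done for the 17 lists with at least 5 such members. The p-values belong to the difference in means, and medians are printed beside them. Shares have 95% exact binomial intervals (Clopper-Pearson), which cover counting error only.

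Genes named in the text followed a rule fixed beforehand. They were *Hnf1b*, *Hnf1a* and *Hnf4a*, every gene of the list of reported targets, the gene with the nearest end to each of the 15 strongest shared sites, and from every other list up to 4 members with the strongest site within 10 kb. Not all of these are printed, and genes named outside the rule are marked as such.

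Calculations were tested on simulated data. For the count of shared sites, 14982 of 15000 planted sites were recovered. For overlap, 60.1% of events were found shared where 60% had been planted. For gene lists, 1000 random lists of 30 genes among 21883 were called at an unadjusted p under 0.05 in 5.1% of draws with no effect, in 55.9% with a planted odds ratio of 2 and in 98.1% with one of 4. In these simulations each gene had a site independently of its neighbours, its length and the gene density around it. They therefore do not show the rate of false calls where neighbouring genes share sites.

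Alternatives fixed beforehand left out each library in turn, required a −log10 q of at least 3, took the same number of strongest events per library, required 2 or 3 libraries, chained within 50 or 200 bp, shifted events by up to 10 kb, used gene windows of 500 bp, 1 kb, 5 kb or 50 kb, and drew random lists matched on gene density and gene length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.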

Results

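Binding of HNF1B, a homeodomain transcription factor of kidney, liver and pancreas epithelia, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole kidneys of wild-type male mice aged 60 days. The series comprised 5 samples, which were 4 immunoprecipitated libraries and 1 input library. A list of binding events was analysed for each of the 4 immunoprecipitated libraries, and the input was not analysed here. After removal of events outside chromosomes 1 to 19, X and Y, the lists of libraries 1, 2, 3 and 4 held 84054, 39478, 28900 and 35088 events, a mean of 46880 ± 25160 (SD, n = 4). The median deposited signal per event was 197 in library 1, 145 in library 2, 148 in library 3 and 86 in library 4. The read depth of the libraries was not given in the sources used here. The stated purpose of the series was to define the genes under HNF1B control in the adult kidney, so the comparisons below concern which sites recurred between libraries and which genes lay next to them.

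The genes encoding HNF1B and its close relative HNF1A both carried recurrent sites. *Hnf1b* (mm10 chromosome 11, 83850209 to 83905917) had 4 sites within 10 kb of its ends, and the strongest lay at 83852823, inside the gene and 2614 bp from its nearer end, with a strength of 3.92 ± 0.71 (SD, n = 4). Strength is the signal of a site over the median signal of the same library at all sites shared by the 4 libraries. *Hnf1a* (chromosome 5, 114948980 to 114971062) also had 4 sites, the strongest at 114968697 with a strength of 3.90 ± 0.94 (SD, n = 4). *Hnf4a*, which encodes a nuclear receptor of proximal tubule and liver, had none within 10 kb of its ends but 6 inside its span, the strongest at chromosome 2, position 163540932 (3.84 ± 0.68, SD, n = 4).

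Of 16 genes listed beforehand as reported HNF1B targets, 13 had a shared site within 10 kb of an end (81.2%), against 29.6% of all other protein-coding genes (odds ratio 9.17, Fisher's exact test, two-sided, adjusted p = 0.000166). The strongest sites of these 13 genes were stronger than those of other genes with a site, with a median strength of 3.09 against 1.19. A permutation test of the difference in mean log2 strength (1.27) gave p = 0.0001, the smallest random lists can give in 10000 draws (adjusted p = 0.00085 over 17 lists, two-sided). *Wnt9b*, a ligand of nephron induction, had the strongest of them (5.55 ± 0.75, SD, n = 4). It was followed by *Pde4c*, a cyclic AMP phosphodiesterase (4.84 ± 0.83), *Pkhd1*, the gene of autosomal recessive polycystic kidney disease (4.57 ± 0.83), *Kif12*, a kinesin (4.54 ± 1.07), *Pax2*, a transcription factor of kidney development (4.51 ± 1.05), and *Umod*, which encodes uromodulin of the thick ascending limb (4.50 ± 0.74). The *Pkhd1* site at chromosome 1, position 20618114, lay 32 bp outside the gene, and the *Umod* site at chromosome 7, position 119479456, lay 194 bp outside.

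Intermediate strengths were found at *Bicc1* (3.09 ± 0.86), *Pkd2* (3.07 ± 0.04), *Fxyd2* (2.93 ± 0.69), *Kcnj16* (2.69 ± 0.90) and *Glis2* (2.304 ± 0.22). *Cltrn*, which encodes collectrin (1.19 ± 0.29), and *Socs3*, a cytokine signalling inhibitor (0.77 ± 0.09), lay near the typical shared site, all with n = 4. The 3 listed targets without a shared site within 10 kb of an end were *Hnf4a*, *Ift88* and *Lhx1*. The shared site nearest to an end of *Ift88* was 16.2 kb away and that of *Lhx1* was 75.3 kb away. Within 10 kb of an end lay a site called in 3 libraries at *Ift88*, one in 2 libraries at *Lhx1* and one in 1 library at *Hnf4a*.

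**Figure D1:**
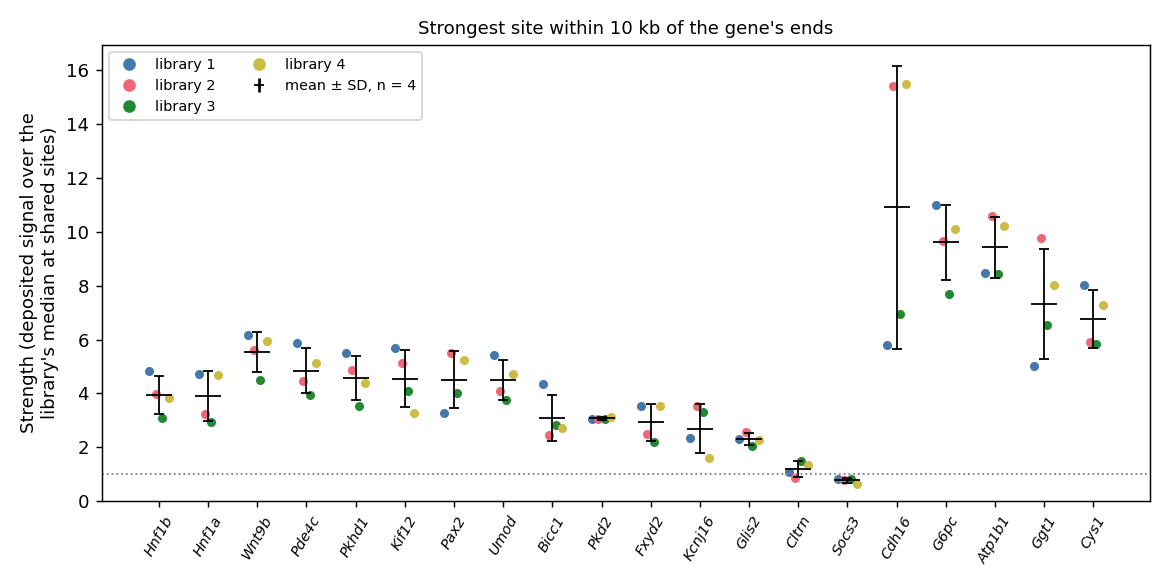
Strength of the strongest shared site within 10 kb of the ends of 20 genes. The vertical axis is the deposited signal over the library's median at shared sites, coloured points are the 4 libraries, and black bars are the mean ± SD; *Cdh16* has the widest spread, from 5.80 to 15.5.

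Among the 15 strongest shared sites, those next to named kidney genes lay at *Cdh16*, *G6pc* and *Atp1b1*. The site at *Cdh16*, the kidney-specific cadherin, was at chromosome 8, position 104624364, 32 bp inside the gene's end, with a strength of 10.9 ± 5.27 (SD, n = 4). Its values were 5.80, 15.4, 6.95 and 15.5 in libraries 1 to 4, and library 1 held 2 events at this site where each other library held 1. The site 5211 bp outside *G6pc*, the glucose-6-phosphatase of gluconeogenesis, had a strength of 9.62 ± 1.39, and the site 2758 bp outside *Atp1b1*, a sodium pump subunit, had 9.42 ± 1.14 (SD, n = 4). Others lay inside *Rassf7* and 939 bp from *Lmntd2* (10.0 ± 2.04), 26.6 kb from *Zfp36l2* (9.56 ± 2.06) and inside *Arhgap24*, 87.2 kb from its nearer end (9.31 ± 1.59). The remaining 9 of the 15 fell into 2 stretches, chromosome 8 from 19619212 to 20917824 and chromosome 5 from 14954306 to 15781255, whose nearest genes were *Gm21119*, *Gm15319*, *Defb33*, *9530057J20Rik*, *Gm17019* and *Speer4c*. No gene of the fixed lists was among the 8 and 7 protein-coding genes of these stretches, which is likely for so few genes. In libraries 2, 3 and 4 the 25 shared sites of the stretches had on median a lower deposited significance than shared sites of the same signal. In library 1 the median difference was 0, with 18 of the 25 at the upper limit.

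Binding sites recurred between the 4 libraries far more often than by chance. Chaining event positions no more than 100 bp apart gave 82829 sites, of which 22886 (27.6%) were called in all 4 libraries, 8595 in 3, 11685 in 2 and 39663 in 1. When the lists of 3 libraries were shifted along the chromosomes, a mean of 0.01 sites was called in all 4. On average 74.1% ± 21.6 of the events of a library had an event of another library within 100 bp, 218-fold ± 41.8 above shifted lists (SD, n = 4), a comparison that takes the lists as separate calls, which the sources used here did not state. Each library's value was an average over its pairs with the others, so the 4 values rest on the same pairs of lists and are not independent. Library 1 had the lowest fold, 156, and it alone called 37124 of the sites found in 1 library. At shared sites, log2 signal correlated between libraries with Pearson's r from 0.882 to 0.920 over 6 pairs, a correlation across sites, which are not independent replicates. The median coefficient of variation of strength over the 4 libraries was 15.7%. The fold over chance moved by more than 1.5 times with the shift model, the distance that counted as shared and the length of the lists, from 64.2 when events were shifted by up to 10 kb to 408 when they were chained within 50 bp. It was 348 ± 7.39 (SD, n = 4) with the same number of events per library.

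**Figure D2:**
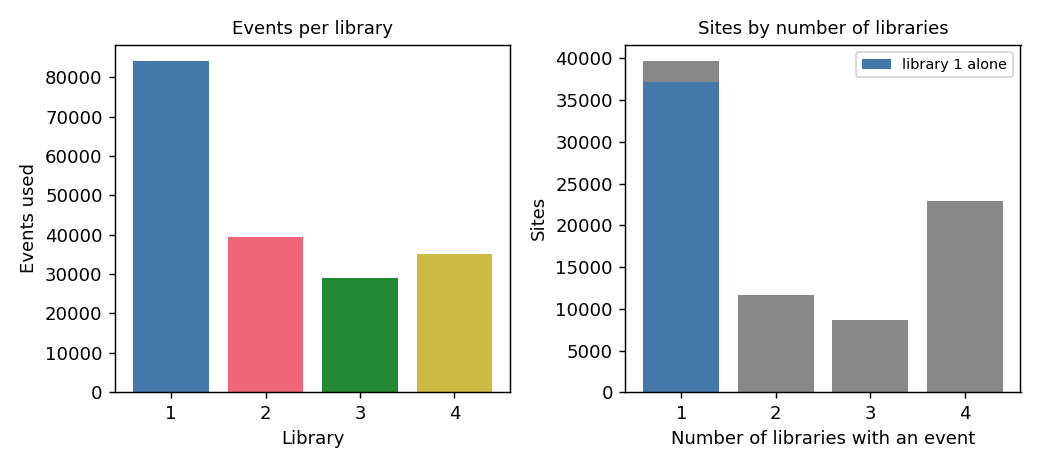
Left, the number of events per library, from 28900 in library 3 to 84054 in library 1. Right, the number of sites by how many libraries called them, with the 37124 sites of library 1 alone in blue.

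Proximal tubule genes were the most completely covered of the 23 gene lists. Of 50 proximal tubule markers, 47 had a shared site within 10 kb of an end (94.0%, 95% exact binomial interval 83.5 to 98.7%), against 29.5% of other genes (odds ratio 32.5, Fisher's exact test, adjusted p = 2.16e-20). The odds ratio ranged from 10.1 with sites over 1 kb from gene ends to 105 with sites in at least 2 libraries. Examples were *G6pc* (9.62 ± 1.39), *Ggt1*, a glutathione-degrading brush border enzyme (7.34 ± 2.04), and *Slc6a19*, the neutral amino acid transporter (4.89 ± 0.69, SD, n = 4), whose strongest site also lay within 10 kb of its neighbour *Slc6a18*. The 3 members without one were *Slc7a8*, *Slc9a3* and *Gatm*, named after their values were seen. Deeper inside their spans, *Slc9a3* held 4 shared sites and *Slc7a8* held 2. The strongest sites of proximal tubule genes were also stronger than those of other genes with a site (median 2.17 against 1.18, permutation test with random lists, adjusted p = 0.00085, from p = 0.0001, the smallest random lists can give).

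Thick ascending limb genes had a shared site in 13 of 20 cases (65.0%, odds ratio 4.28, Fisher's exact test, adjusted p = 0.00768), among them *Umod* (4.50 ± 0.74), *Tmem72* (4.44 ± 0.83), *Tmem207* (4.20 ± 0.92, or 6.67 ± 0.82 with the signal of all its events summed) and the claudin *Cldn14* (4.14 ± 0.59, SD, n = 4). The strongest sites of the genes of this list had a median strength of 2.14 (permutation test with random lists, adjusted p = 0.0399). Genes of the distal convoluted and connecting tubule had one in 12 of 20 cases (60.0%, odds ratio 3.50, exact test, adjusted p = 0.0180). Their strongest sites were at *Wnk4* (3.92 ± 0.56) and *Klhl3* (3.24 ± 0.81), regulators of the sodium chloride cotransporter, then *Fxyd2* (2.93 ± 0.69) and *Trpm7* (2.73 ± 0.27, SD, n = 4). The strongest sites of the genes of this second list were not called stronger (median 1.95, permutation test with random lists, adjusted p = 0.160). The call of this second list was lost under 8 of the 17 alternatives. Among these were that without replicate 3 (exact test, adjusted p = 0.0604) and random lists matched on gene density and length (odds ratio 2.61, permutation test, adjusted p = 0.0895). Over all 17, kept or lost, odds ratios ranged from 2.32 to 4.11 and adjusted p from 0.00721 to 0.207, both ends in exact tests. The thick ascending limb call was lost when sites within 1 kb of gene ends were left out (exact test, adjusted p = 0.108, range 0.00144 to 0.108).

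Collecting duct genes did not share this pattern. Of 25 members 5 had a shared site (20%, interval 6.83 to 40.7%, odds ratio 0.637, Fisher's exact test, adjusted p = 0.440, with an odds ratio of 1.36 for a 1 kb and 1.10 for a 50 kb window). This share was below those of proximal tubule (adjusted p = 3.55e-10), thick ascending limb (adjusted p = 0.00585) and distal tubule genes (adjusted p = 0.0122) in exact tests between lists, 8 of which were run. The members with the strongest sites were *Tfcp2l1*, a transcription factor of intercalated cells (1.98 ± 0.22), *Aqp4* (1.23 ± 0.24), *Fxyd4* (1.11 ± 0.15) and *Car2* (1.08 ± 0.11, SD, n = 4). The water channel gene *Aqp2* and the sodium channel genes *Scnn1a*, *Scnn1b* and *Scnn1g*, named after their values were seen, had none. *Slc14a2* and *Slc26a4*, also named then, had none within 10 kb of an end but held 10 and 2 deeper inside their spans.

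Genes of the other cell types a kidney holds, and of tissues other than kidney, were not called in either direction. Podocyte genes had a shared site in 8 of 20 cases (exact test, adjusted p = 0.400), with the strongest at *Nphs1*, which encodes nephrin (3.58 ± 0.37), and *Clic5* (2.24 ± 0.43). Endothelial genes had one in 4 of 20 (exact test, adjusted p = 0.509), among them *Ptprb* (5.45 ± 1.24) and *Esam* (3.96 ± 0.75). Stromal and fibrosis genes had one in 3 of 20 (exact test, adjusted p = 0.316), with 0.90 ± 0.17 at *Tgfbr2*, and immune genes in 2 of 22 (adjusted p = 0.0733), *Csf1r* (1.14 ± 0.10) and *Cd4* (0.45 ± 0.04), SD and n = 4 throughout. Of the lists for tissues other than kidney, hepatocyte genes had one in 16 of 35 (exact test, adjusted p = 0.0810), with *Afp* and *Afm* next to the same site (3.33 ± 0.46). Neuronal genes had one in 3 of 25 (exact test, adjusted p = 0.135), *Nefh* being highest at 0.85 ± 0.02, and striated muscle genes in 4 of 25 (adjusted p = 0.308), *Tnni1* being highest at 1.71 ± 0.18. In the events of single libraries, neuronal genes were called lower in libraries 2 and 4 (exact test, adjusted p = 0.0231 and 0.0437), stromal genes in library 2 (0.0454), immune genes in library 3 (0.0278) and striated muscle genes in library 4 (0.0212). Of the 17 alternatives, 5 called immune genes lower, among them that without replicate 4 (exact test, adjusted p = 0.0487, lowest 0.0188). Neuronal genes were called lower under 2, without replicate 3 (exact test, adjusted p = 0.0286) and with support of 3 libraries. Striated muscle genes were called lower with support of 2 or 3 libraries (exact test, adjusted p = 0.0345 and 0.0425). Hepatocyte genes were called higher with equal numbers of events (exact test, adjusted p = 0.0263).

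**Figure D3:**
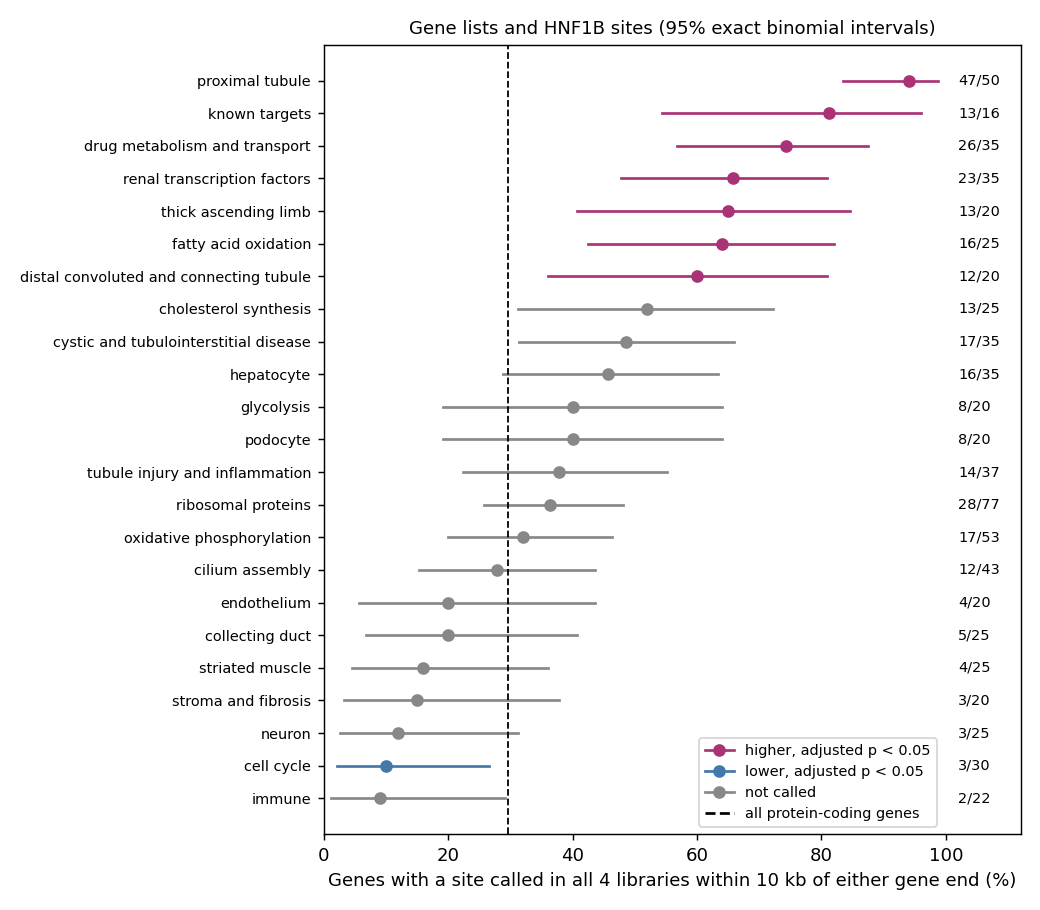
Percentage of each fixed gene list with a site shared by the 4 libraries within 10 kb of either gene end. Points are observed shares, lines are 95% exact binomial intervals, digits are members with a site over members tested, and the dashed line is the 29.6% of all protein-coding genes. Lists at the top, led by proximal tubule at 94.0%, lie to the right of that line.

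Genes of kidney transcription factors and of substance handling were covered more than other genes. Among 35 renal transcription factor genes 23 had a shared site (65.7%, odds ratio 4.48, Fisher's exact test, adjusted p = 0.000117), including *Pax2* (4.51 ± 1.05), *Emx2* (4.05 ± 0.59) and *Pax8* (3.95 ± 0.53, SD, n = 4). Drug metabolism and transport genes had one in 26 of 35 cases (74.3%, odds ratio 6.65, exact test, adjusted p = 7.17e-07), led by *Abcc2*, an organic anion exporter (4.36 ± 0.79), the glutathione transferase *Gsta2* (3.42 ± 0.48) and *Cyp2j5* (3.29 ± 0.85). Fatty acid oxidation genes had one in 16 of 25 cases (64.0%, odds ratio 4.13, exact test, adjusted p = 0.00247), led by the acyl-CoA dehydrogenase *Acadl* (5.08 ± 0.76) and *Crot* (2.83 ± 0.27). The strongest sites of the genes of the first of these lists had a median strength of 1.98 (permutation test with random lists, adjusted p = 0.0132) and those of the second 1.93 (adjusted p = 0.0150), while those of the third, 1.76, were not called stronger (adjusted p = 0.382). With a window of 1 kb in place of 10 kb, the transcription factor (exact test, adjusted p = 0.820) and fatty acid oxidation (adjusted p = 0.239) calls were lost, the highest adjusted p of either list over the 17 alternatives.

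The disease lists and the remaining pathways did not pass the threshold, except for cell cycle genes. Cystic and tubulointerstitial disease genes had a shared site in 17 of 35 cases (48.6%, odds ratio 2.25, Fisher's exact test, adjusted p = 0.0587). In the events of each library taken alone the list was called, with adjusted p from 0.00214 to 0.0238 in exact tests, and the strongest shared sites of its genes had a median strength of 2.00 (permutation test with random lists, adjusted p = 0.00623). The strongest were at *Cys1*, the cystin gene (6.76 ± 1.07), and *Nek8* (4.63 ± 0.96), whose site also lay within 10 kb of *Rpl23a*. *Pkhd1* (4.57 ± 0.83) and *Umod* (4.50 ± 0.74) came next, and both are also on the list of reported targets. Tubule injury and inflammation genes had one in 14 of 37 (exact test, adjusted p = 0.382), with *Itgb6* (4.28 ± 0.28), complement *C3* (3.95 ± 0.58) and *Itgb8* (3.61 ± 0.91, SD, n = 4) highest. The counts were 13 of 25 for cholesterol synthesis (exact test, adjusted p = 0.0587, *Hmgcs1* 3.12 ± 0.21, called in each library alone with adjusted p from 0.000682 to 0.0297), 8 of 20 for glycolysis (adjusted p = 0.400, *Ldhb* 3.07 ± 0.23) and 12 of 43 for cilium assembly (adjusted p = 0.869, *Ift74* 1.67 ± 0.35, but called in library 1 alone with 38 of 43, adjusted p = 0.00611). They were 17 of 53 for oxidative phosphorylation (exact test, adjusted p = 0.798, *Sdhd* 3.31 ± 0.55) and 28 of 77 for ribosomal proteins (adjusted p = 0.316, *Rps19* 3.77 ± 0.80). In the events of single libraries, ribosomal protein and oxidative phosphorylation genes were called higher in libraries 1, 2 and 4 and not in library 3. Library 1 had an event at 73 of 77 ribosomal protein genes and at 68.1% of all genes, and library 3 at 31 and at 34.1%. With lists of equal length the counts were 49 and 31. Of the 17 alternatives, 5 each called ribosomal protein, cholesterol synthesis and cystic disease genes higher, and 1, sites in at least 2 libraries, called oxidative phosphorylation genes higher (odds ratio 2.84, exact test, adjusted p = 0.00177). Ribosomal protein genes were called without replicate 3 (exact test, adjusted p = 0.0111) and against random lists matched on gene density and length (odds ratio 2.55, permutation test, adjusted p = 0.00115). Cholesterol synthesis genes were called without replicate 3 (exact test, adjusted p = 0.00715). Cystic disease genes were called without replicate 2 (exact test, adjusted p = 0.0279), without replicate 4 (0.0431) and with a 1 kb window (odds ratio 6.02, 0.000181). They were weaker against matched random lists (odds ratio 1.66, permutation test, adjusted p = 0.235) and with sites over 1 kb from gene ends (1.96, exact test, adjusted p = 0.181).

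Cell cycle genes had a shared site in 3 of 30 cases, *Birc5* (2.75 ± 0.36), *Tyms* (1.04 ± 0.17) and *Bub1* (0.40 ± 0.09, SD, n = 4), fewer than other genes (10.0%, odds ratio 0.302, Fisher's exact test, adjusted p = 0.0457). The direction turned when sites in at least 2 libraries were used (odds ratio 1.35) and with a 50 kb window (1.99). The call was kept under 8 of the 17 alternatives, and over all 17 adjusted p ranged from 0.00862 to 0.511 in exact tests. It was lost without replicate 3 (exact test, adjusted p = 0.123), against matched random lists (permutation test, 0.0517) and with list membership rotated along the genes (permutation test, 0.0621). In the events of library 1 alone, 28 of the 30 cell cycle genes had one (odds ratio 5.36, exact test, adjusted p = 0.00465). Across the 23 lists 7 were higher, 1 was lower and 15 were not called after adjustment, and 12 had an unadjusted p under 0.05. When the same lists were tested against shifted sites, a mean of 0.17 lists was higher and 0.02 lower over 100 shifts. The highest counts in a single shift were 4 lists higher and 1 lower, as many lower as were observed.

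Most shared sites lay away from the ends of genes. Within 1 kb of the end of a protein-coding gene were 1561 of 22886 shared sites (6.82%, 95% exact binomial interval 6.50 to 7.16%), 2.20-fold more than the 3.101% of shifted sites. A further 25.6% lay 1 to 10 kb away, 35.2% lay 10 to 50 kb away and 32.4% lay more than 50 kb away, the last against 49.2% of shifted sites. Inside the span of a protein-coding gene were 52.6%, against 40.7% of shifted sites. The strongest 10% of shared sites lay within 1 kb of a gene end more often than the weakest 10% (8.30% against 3.23%, odds ratio 2.71, Fisher's exact test over sites, p = 1.3e-13). There was no steady gradient between them. The share was highest, 8.74%, in bin 6 of 10 counted from the strongest, and it fell below 6.64% in the 2 weakest bins alone. Over the full lists, the share within 1 kb was 12.0% in library 1, 10.9% in library 2, 7.24% in library 3 and 10.3% in library 4, a mean of 10.1% ± 2.03 (SD, n = 4). Sites called in libraries 1, 2 and 4 without library 3 had a share of 19.5%, and sites called in at least 2 libraries 10.8%, 1.5 times or more above that of sites shared by all 4. Among other sites of 3 libraries it was 7.61% (libraries 1, 2 and 3), 8.69% (1, 3 and 4) and 21.0% (2, 3 and 4, 62 sites). Sites called in 1 library alone had 13.7%, 28.8%, 16.5% and 21.0% in libraries 1 to 4, so high shares were not limited to sites of libraries 1, 2 and 4.

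**Figure D4:**
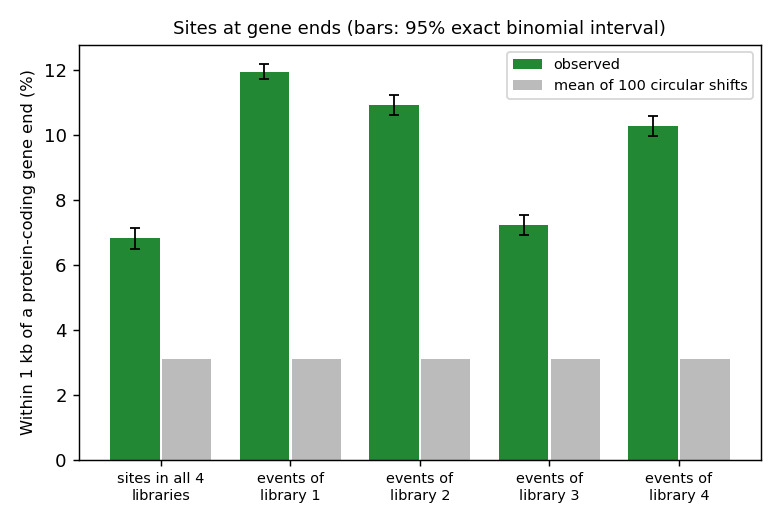
Percentage of shared sites, and of the events of each library, within 1 kb of the end of a protein-coding gene. Green bars are observed shares with 95% exact binomial intervals, grey bars are the means of 100 circular shifts; library 3 is lowest of the libraries at 7.24% and library 1 highest at 12.0%.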

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

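The patterns weighed here were picked after the data were seen, and the outcome that each explanation predicted was written down before its test was run, except for the kinds of genes at ends with a site missing from library 3, a test chosen after the results were seen, and that sites at the upper limit of significance were kept in the test of the 2 stretches was also chosen then. For 141 sets of 4 library values (12 library summaries, 23 gene lists and 106 sites of named genes) the gap of the outermost library to its neighbour was divided by the range. In 11 sets it passed the critical value of Dixon's test, and chance alone gives about 5% of sets. These were 2 of the 12 library summaries, 3 of the 23 gene lists and 6 of the 106 sites of named genes. The number for named genes is near what chance alone gives.

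Library 1 stood apart in 8 of the 11. It had 3134 events at the upper limit of significance against 43, 7 and 2 (gap over range 0.987), and its overlap fold over shifted lists was 156 against 235, 248 and 235 (0.861). With the same number of events per library the mean fold was 348 ± 7.39 (SD, n = 4), so the libraries lay close together once list length was equal. Its log2 odds ratio was 2.66 for the cystic disease list against 1.53, 1.36 and 1.33 (0.850), 2.76 for oxidative phosphorylation against 0.95, 0.79 and 1.01 (0.889), and 0.49 for neuronal genes against −1.66, −1.30 and −1.49 (0.836). Its strength was also apart at *Egfl7* (2.76, gap 0.861), *Rplp0* (2.53, gap 0.846) and *Stard4* (3.11, gap 0.940). Library 4 was apart at *Tgfbr2* with 1.15 against 0.81, 0.82 and 0.83 (gap 0.948). Library 3 was apart at the sites on chromosome 5, position 15054306 (6.67, gap 0.901) and chromosome 8, position 20024388 (6.51, gap 0.905).

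Events on scaffolds outside the assembled chromosomes, which no comparison used, numbered 28, 6, 5 and 5 in libraries 1 to 4, above the 3 that a count of 0 allows.

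The lists differed in length and in the share of events at gene ends, and length did not account for the gene end shares by itself, because the highest share was 1.93 times the lowest after every list was reduced to its 28900 strongest events, against 1.65 times in the full lists. More reads per event in library 1 may account for its length. Events that it alone called had a median signal of 117 against 537 at shared sites. Its reduced list was shared with the others as often as they were with each other (difference −0.0173 percentage points). Both outcomes were those predicted, but any cause that adds weak events to a list would give them too. Read depth was not given, so they do not tell such causes apart. Whether the low share in library 3 reflects ends of broadly used genes cannot be told apart from other causes, since ribosomal, oxidative phosphorylation and cell cycle genes were 12 of 1008 genes with an end site in libraries 1, 2 and 4 alone and 16 of 1483 with one in all 4 (odds ratio 1.12, Fisher's exact test, adjusted p = 0.847 over 2 tests; the other, of tubule genes, 1 against 42 with odds ratio 0.0505 and adjusted p = 2.05e-08, decides nothing because those lists had already been called at sites of all 4 libraries). The design has 1 condition, so no biological explanation was tested.

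Of the 50 strongest shared sites, 14 lay in 2 stretches of chromosomes 5 and 8 that hold defensin, *Speer* and unnamed gene models. Their 7 and 8 protein-coding genes included no gene of the fixed lists, which is likely for so few genes and does not set the stretches apart. A candidate explanation is reads piled up from extra or near-identical copies that a control library also shows, which would lower the deposited significance at a given signal. The median difference in log10 of −log10 q from shared sites of equal signal was −0.154 in library 2, −0.203 in library 3 and −0.117 in library 4, which is in line with it. Library 4 had none of the 25 at the upper limit, library 3 had 3 and library 2 had 11, and library 1, with 18, had a median of 0. Which control library the authors used was not given in the sources used here, and no biological explanation was tested.

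Collecting duct genes had few shared sites. Binding in a minority of the cells of a whole kidney could leave sites that pass in fewer libraries. Of 20 collecting duct genes without a shared site within 10 kb of an end, 12 had a site of lower support there, against 56.1% of other such genes (odds ratio 1.15, one-sided Fisher's exact test, p = 0.453). With 20 genes the explanation cannot be told apart from no difference. In the same test 7 of 7 thick ascending limb genes had such a site (odds ratio 11.8, one-sided Fisher's exact test, unadjusted p = 0.0174), as did 7 of 8 distal tubule and 16 of 22 neuronal genes. The counts were 8 of 16 for endothelial, 10 of 20 for immune and 10 of 21 for striated muscle genes. The readout was thus also raised for lists with many shared sites, so it could not by itself mark binding in a minority of cells. The design names no group with which to test a biological explanation.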

How the results depend on the processing

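The alternatives without the 2 stretches of chromosomes 5 and 8, with whole gene spans, with sites over 1 kb from gene ends only, with rotated lists and with summed signal were chosen after seeing the data. Proximal tubule, reported target and drug metabolism lists were called higher under each of the 17 alternatives, and the number of higher lists ranged from 5 to 10. Their odds ratios ranged from 10.1 to 105, from 5.27 to 10.8 and from 5.44 to 14.6. Those of thick ascending limb (2.69 to 8.25), distal convoluted and connecting tubule (2.32 to 4.11), renal transcription factor (1.37 to 5.90) and fatty acid oxidation genes (2.67 to 17.0) also moved by over 1.5 times. The number of sites was 22981 to 27920 without 1 library and 43166 when 2 libraries sufficed. The fold over chance was 189 to 286 without 1 library, the upper value without replicate 1, 348 with the same number of events per library, 408 with a chain of 50 bp, 114 with 200 bp and 64.2 with shifts up to 10 kb; chance overlap itself grows with the distance allowed. The share near gene ends was 6.88 to 9.07% without 1 library, the upper value without replicate 3, 7.30% with equal numbers of events, 10.8% and 8.97% with support of 2 and 3 libraries, and 4.61% and 20.8% for windows of 500 bp and 5 kb, by construction.

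Odds ratios that changed side, none of them past the threshold, were those of collecting duct (1.36 at 1 kb and 1.10 at 50 kb), ribosomal proteins (0.974 with gene spans), oxidative phosphorylation (0.811 with gene spans and 0.524 without gene end sites), cell cycle (1.35 with 2 libraries and 1.99 at 50 kb) and cilium assembly. The last was 0.904 to 1.26 without 1 library, the upper value without replicate 3, 1.11 with equal numbers, 1.31 and 1.24 with support of 2 and 3 libraries, and 1.10 and 1.17 at 1 kb and 50 kb. The cause was not tested. Of the list values that kept their side, 334 kept their readout, 26 were called where the chosen analysis had no call and 18 lost their call. Of the strengths of named sites 876 moved by less than their SD and 139 by more. Leaving out 1 of 4 libraries cannot move a mean by its SD, apart from a change in the medians used for scaling. These counts are therefore a weak test of stability. Of the 114 entries for named sites, 4 with equal numbers of events, 5 with a chain of 50 bp and 2 with 200 bp had no site within 100 bp and are not in these counts. With summed signal the site at *Cdh16* had 11.8 ± 4.08, while those near *Tmem207* (6.67 ± 0.82) and 410 bp from *Zfp36l2* (1.74 ± 0.14) moved by over 1.5 times.

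Searches for the HNF1 sequence were not run, and the other alternatives not run were those limited to sites with that sequence and those with 1 transcription start per gene. No paired analysis was possible because a single group had lists. Read depth was not given in the sources used here, so weak sites missing from libraries 2 to 4 cannot be separated from sites below detection.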

Other observations

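The tests in this part were chosen after the data were seen. Solute carrier genes had a shared site more often than other genes. Of 375 protein-coding genes whose symbols start with *Slc* and a digit, 188 had a shared site within 10 kb of an end (50.1%, odds ratio 2.43, Fisher's exact test, adjusted p = 1.63e-15), a count that includes members of the fixed lists. Symbol families were formed from the letters before the first digit, which need not match protein families. Among 78 symbol families of at least 25 genes, 4 others were higher: *Dnajc* co-chaperones (17 of 28, exact test, adjusted p = 0.00438), *Polr* polymerase subunits (16 of 28, adjusted p = 0.0150), *Rab* symbols (31 of 69, adjusted p = 0.0344) and *Snx* sorting nexins (16 of 30, adjusted p = 0.0344). The lower families numbered 13, among them olfactory receptors (*Olfr*, 43 of 1110, odds ratio 0.0906), vomeronasal receptors (*Vmn*, 6 of 355, odds ratio 0.0432) and keratins (*Krt*, 1 of 53, odds ratio 0.0676). Olfactory receptor, vomeronasal receptor and keratin genes lie in clusters, so the p-values of such families, not printed here, are too small. How far genes of the higher families lie in clusters was not examined, and their p-values may be too small as well.

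Joining shared sites no more than 12.5 kb apart, without the 2 stretches of chromosomes 5 and 8, gave 15546 regions, of which 11038 held 1 site and 299 held 5 or more. The highest summed strength was 21.7 over 11 sites on chromosome 5 from 148956351 to 149002640, 27183 bp from *Katnal1*, followed by a region of 12 sites at *3110040M04Rik* (21.1). A region of 9 sites on chromosome 2 from 170451154 to 170475525 lay 7432 bp from *Cyp24a1*, which encodes the vitamin D 24-hydroxylase (summed strength 18.5). Next came regions overlapping *Zmiz1* (9 sites, 18.3), *Tead1* (7 sites, 17.4), *Smad7* (4 sites, 17.2) and the ciliary gene *Dcdc2a* (6 sites, 17.2), and at rank 9 a region of 8 sites lay 15003 bp from *Kap*, the androgen-regulated kidney protein gene (16.6).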
